A study of Mus musculus with 2 samples.

How the data were processed

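The samples were bone marrow cells of male CByB6F1 mice. Per the labels' protocols, cells were filtered through a 100 µm mesh, large cells were collected from the top of a 10 µm strainer, and the enriched cells were fixed and prepared with a split-pool single-cell kit, with cells of 20 BMF mice at day 14 pooled as a BMF group and of 10 normal mice as a control group. The deposited values are counts of molecules (UMIs) per gene and barcode. They were checked to be whole and at least 0. HISAT2 2.0.5 and the genome build mm10 are named in the submitters' processing notes; their role, the counting step, the gene annotation and any earlier filter on barcodes are not given in the sources used here. Each barcode is written as 3 numbers, the first from 1 to 12 and the others from 1 to 96.

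The labels describe both pools as normal and BMF cells together, and the column names carry barcodes with no condition. No cell was given a condition, and the planned comparisons of BMF with normal mice were not made. Nothing says that the pools came from separate animals. Of 405 barcodes of pool 1 with at least 200 genes, 388 (95.8%) also occurred in pool 2, so the pools are not taken as independent replicates. The p-values and SEs therefore measure only the spread between these pools, which may be technical. Chi-square values over genes were 1.28 per degree of freedom between the pools in megakaryocyte-like, 1.63 in macrophage-like and 1.13 in erythroid-like sums. UMIs of a cell are not independent draws, and 1 cell held 14.3% of the macrophage-like sum of pool 2, so these values do not show a difference between the pools.

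The median barcode had 35 UMIs in pool 1 and 36 in pool 2. Barcodes with at least 200 genes and at most 20% mitochondrial counts were kept, with no upper limit on UMIs; they held 55.5% and 59.1% of counts. Scrublet, run per pool with an expected rate of 6%, called 8 and 4 cells doublets, which were kept. Ribosomal-like gene names, 9 in number, held 18.2% and 18.3% of counts. Counts were scaled to 10000 per cell and logged. From the 2000 most variable genes, without mitochondrial genes, ribosomal-like names and gene list members, 20 principal components were computed. Cells were joined to 15 neighbours on 15 components and grouped by the Leiden method at resolution 1 (scanpy 1.11.5, igraph 0.11.9, Python 3.11.15).

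A cluster was called X-like where at least 3 markers of a class, making up at least 40% of its list and a larger share than for any other class, were detected in at least 10% of its cells and lay at least 2-fold above the median of the other clusters, with 50 CPM added to both. Markers, gene lists, tests and the rule for named genes were fixed before the data were examined. That rule names, from each list, the 4 members with the highest mean CPM in megakaryocyte-like sums and the 2 with the lowest adjusted p in each direction, and for each cluster the 5 genes with the largest fold over the other cells among those in at least 25% of its cells. Other genes named (Camp, Cd84, Cdk1, H2-K1, Itgb3, Ltf, Ngp, Pdia3, Psmb8 and Tpm4) were chosen after their values were seen.

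Several choices were made after seeing the data. Resolution 1 was picked after 0.5 and 1.5 had been looked at. The naming rule used at first asked for 3 markers and more of them than any other class. It named 13.7% of pool 1 and 12.0% of pool 2 T cell-like (cluster 10) and 8.71% and 8.99% neutrophil-like (cluster 3), and it left the macrophage-like cluster unnamed on a tie of 7 markers. The 40% requirement was added after this was seen and keeps those clusters out of the named classes. The plan asked for at least 50 cells per class and pool; with the final names only the megakaryocyte-like class had these in both pools, and 30 was used. Under the rule used at first the T cell-like class had 55 and 64 cells, so the comparison could have been made as planned; it was run as an alternative. The minimum of 10 counts over the 6 sums was chosen from numbers of genes alone.

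Counts were summed per pool and class. The 4088 genes passing the minimum were tested with edgeR 4.0.16 (quasi-likelihood test, Benjamini-Hochberg adjustment, threshold 0.05) for the contrast of megakaryocyte-like cells with the unweighted mean of the erythroid-like and macrophage-like classes, 3 classes in 6 sums. The SE of a log2 value is its absolute size divided by the square root of the F statistic of that test. Gene lists were tested with camera (limma 3.58.1, R 4.3.3) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 12 lists, and with an estimated correlation.

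The scaling was changed after real results had been seen with TMM over all genes. On simulated sums with 200 changed genes, in 10 draws for this contrast and about 3628 genes, 11.0% of calls with that scaling were unchanged genes, and its factors were off by -0.27 on the log2 scale. TMM factors from genes with at least 5 counts expected in the smallest sum (264 genes in the real sums) were off by 0.01, with 1.47% of calls unchanged genes, and were used instead. Library totals, off by 0.06, had 1.34%. With sums simulated to differ in composition, unchanged genes were 4.39% of calls with TMM over all genes (off by -0.17), 2.59% with the scaling used, 1.88% with DESeq2 size factors and 88.9% with library totals (off by 1.21). DESeq2 size factors did about as well, off by -0.06 with 1.56%, so the simulation does not choose between them, although they place the median of all real genes on opposite sides of 0. The simulation also assumes that most genes do not differ. In it, 97.0% of genes seeded 8-fold higher, 52.6% of those 4-fold higher and 9.76% of those 2-fold higher were recovered, and 53.8%, 35.1% and 8.13% of those lower by the same folds.

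Shares of cells with a UMI were taken after thinning each cell to 200 UMIs, with erythroid-like cells beside them. Thinning was 1 random draw per cell, and the intervals do not cover the spread between draws. The erythroid-like class was planned as a background; its own MHC class I counts need not be background, so it is used as a comparison only. A T cell-like class, planned as a further background, did not exist under the final names. Levels by first barcode number, in the ranges 1 to 6 and 7 to 12, were taken after seeing the data and without a test. Shares carry exact Clopper-Pearson 95% intervals and summed counts exact Poisson 95% intervals, which cover counting error only. For list medians, classes at 0 counts were also set to 3 counts. Gene positions are from GENCODE M21 on mm10, in which 86.1% of gene names matched 1 gene. Alternatives planned beforehand changed the cell filters, doublets, resolution, clustering genes, scaling, test (DESeq2 1.42.0), low-count filter, pools, block and thinning. Added after seeing the data were further scalings and filters, removal of barcodes sharing numbers with a far larger one, removal of ribosomal-like genes, the naming rule used at first, the first barcode number as a block, each other class alone, and shares without the clusters following gene length. Values of 2 list members under the alternatives are not reported here; both members stay in the lists and counts.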

Results

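Single-cell RNA profiles were measured in bone marrow cells enriched for large cells, from mice with bone marrow failure (BMF) and normal mice, in 2 libraries called pool 1 and pool 2. Both pools carry the same description, a mixture of normal and BMF cells. Pool 1 held 968687 counts in 8617 barcodes and pool 2 held 1224028 counts in 9820 barcodes. After filtering, 402 cells of pool 1 (median 520 UMIs, or counted molecules) and 534 cells of pool 2 (median 496 UMIs) were kept. The condition of single cells was not analysed here, so every value describes a mixture, and no difference between BMF and normal mice was measured.

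The share of cells per class addressed which cells the enrichment held. Megakaryocyte-like cells, named after the large precursors of platelets, were the most frequent named class in both pools. They made up 28.4% of cells in pool 1 (114 of 402, exact 95% interval 24.0 to 33.0) and 28.7% in pool 2 (153 of 534, 24.9 to 32.7). Erythroid-like cells, of the red cell lineage, made up 9.70% and 9.36%, and macrophage-like cells 8.96% and 6.74%. Unnamed clusters held 53% and 55.2% of cells. Without the unnamed clusters 3, 5, 6 and 10, whose counts follow gene length, megakaryocyte-like cells made up 51.6% (114 of 221, 44.8 to 58.3) and 53.1% (153 of 288, 47.2 to 59.0), so these shares depend on which barcodes count as cells. In each of the 4 groups, over all kept cells, the interval of each pool contained the share of the other pool. Since the pools shared many barcodes, this does not show that independent samples gave the same shares. The strainer, which retained large cells, can set such shares; its effect was not tested.

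The megakaryocyte-like class joined 4 clusters. Cluster 1 was led by Ppbp, Flna, Ache, Alox12 and Pf4, with Ppbp, a platelet chemokine, 29.6-fold above the other cells (20 CPM added to both), and it had 17 of 19 megakaryocyte markers. Cluster 8 (led by Lpin2, Smtn, Gm5608, Ccdc88a and Neat1) had 13 of these markers, and cluster 9 (Ripor3, Src, Pals1, Rsu1 and Fbxw11) had 10. Cluster 4 (Lars2, Crtam, Gm20661, Malat1 and Max) had 11, with the immune genes Crtam and Cd84 among its top 10 genes and Lars2 one of the ribosomal-like gene names. It also had 4 of 15 neutrophil markers (S100a9, Camp, Ltf and Ngp), and it held 15 of the 25 megakaryocyte-like cells with first barcode numbers 7 to 12. The erythroid-like cluster was led by Car2, Ermap, Ncl, Hdgf and Mki67 and had 9 of 16 markers. The macrophage-like cluster was led by Cd74, C1qa, Psap, Ctsb and H2-Ab1 and had 7 of 13 macrophage markers. It also had 7 of 15 neutrophil markers. Their summed level of 10564 and 7099 CPM (counts scaled to the same total within each group of cells summed) exceeded the 3242 and 2938 CPM of the macrophage markers. Among the unnamed clusters, cluster 10 was led by Cfap61, D030025E07Rik, Dpyd, Unc5d and Nell2, and it held the deepest barcode, with 161165 UMIs. Cluster 3 was led by S100a9, cluster 5 by Grid1, cluster 6 by Slit3 and cluster 7 by Calr. Receptor genes of smell, which bone marrow cells are not known to use, had 0.591 times the counts expected from their length in the unnamed clusters together. In megakaryocyte-like cells they had 0.0316 times, with 0.0125 in cluster 1, 0 in cluster 8, 0.124 (0.0722 to 0.198) in cluster 4 and 0.0953 (0.0310 to 0.222) in cluster 9.

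**Figure D1:**
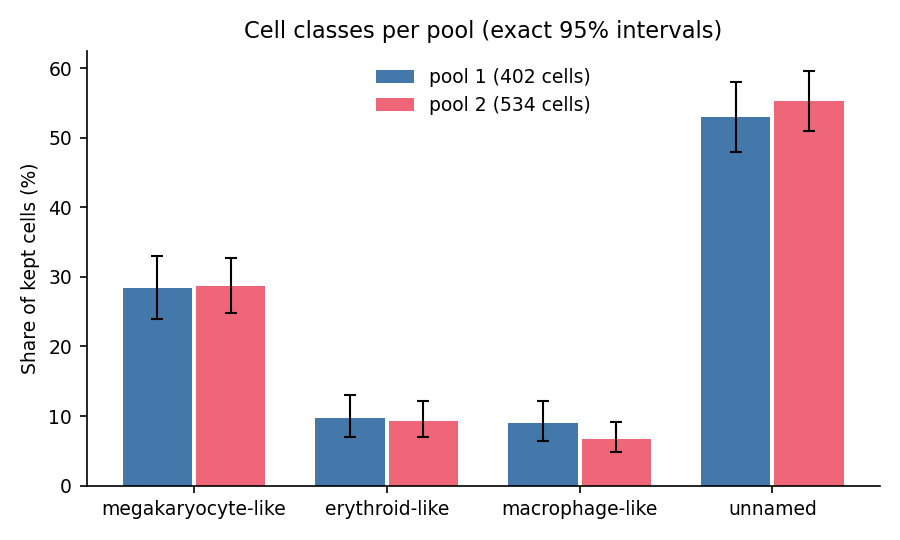
Share of kept cells (%, y axis) per class (x axis) in pool 1 and pool 2, with exact 95% binomial intervals as error bars. Megakaryocyte-like cells took 28.4% and 28.7%.

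**Figure D2:**
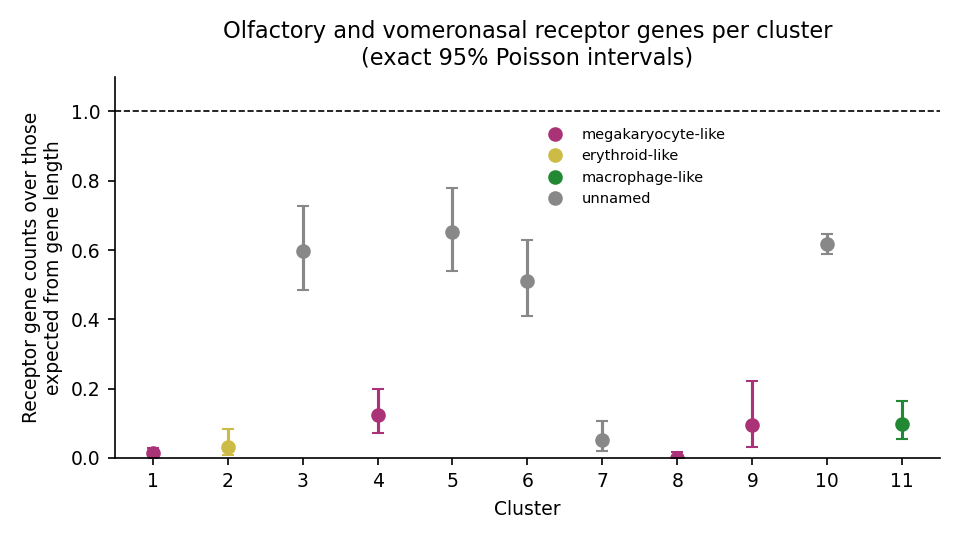
Counts of 328 olfactory and vomeronasal receptor genes over those expected from gene length (y axis) per cluster (x axis, coloured by class), with exact 95% Poisson intervals; the dashed line marks equality. The unnamed clusters 3, 5, 6 and 10 lay between 0.511 and 0.652, cluster 7 at 0.0523, and the megakaryocyte-like clusters 1, 4, 8 and 9 at 0.0125, 0.124, 0 and 0.0953. The macrophage-like cluster 11 lay at 0.0981.

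Megakaryocyte-like cells were set against the erythroid-like and macrophage-like classes, since the study set megakaryocytes beside other blood-forming cells. Genes of the platelet cytoskeleton and granules were higher in megakaryocyte-like cells, at 15139 CPM in pool 1 and 16138 CPM in pool 2, against 1025 and 1182 CPM in erythroid-like and 2795 and 2774 CPM in macrophage-like cells. Stem cell niche factors, at 4010 and 4176 CPM, and megakaryocyte transcription factors, at 4536 and 4148 CPM, were higher as lists too, at the preset correlation. With an estimated correlation no list passed (camera adjusted p = 0.108, 0.228 and 0.300 for these 3). The cell cycle genes Mki67, Top2a and Cdk1 were lower. Of 87 list members tested, 22 were higher and 16 lower (edgeR, adjusted p under 0.05, 6 sums, 3 residual degrees of freedom). With DESeq2 size factors the split was 35 and 7, with TMM over all genes 36 and 6, and with library totals 26 and 11. Under all 4 scalings, 22 members were called higher and 6 lower. The median of all genes was -1.05 on the log2 scale here, -0.43 with library totals, 0.74 with DESeq2 size factors and 0.84 with TMM over all genes, so log2 values below are read against -1.05, or against -0.91 and -1.36 where erythroid-like or macrophage-like cells alone are compared. With sums split by the first barcode number and that number as a block, 19 were higher and 16 lower. The classes differed in that number: erythroid-like cells all had first numbers from 1 to 6, as had 242 of 267 megakaryocyte-like but only 15 of 72 macrophage-like cells.

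Of 13 tested platelet genes, 11 were higher and 1 lower, by adjustment over all genes tested and adjusted over the list alone. Myh9, the non-muscle myosin heavy chain (mm10 chromosome 15, 77760587 to 77842175), reached 4526 and 5091 CPM and was higher by 2.31 ± 0.23 (log2, SE, 2 pools). Vcl, encoding vinculin (chromosome 14, 20929398 to 21033676), was higher by 2.94 ± 0.34. F5, coagulation factor V (chromosome 1, 164151838 to 164220277), had 125 and 234 counts in megakaryocyte-like sums and 1 count in the other 4 sums together. Flna, which led cluster 1, and Tln1 and Tpm4, among its top 10 genes, stayed in the list but describe that cluster. Sparc, with 13 counts in the macrophage-like sum of pool 2 and at most 2 in any other sum, was the lower member and was not called by the other scalings. The list's camera adjusted p (limma) was 3.97e-09; the adjusted p was 0.108 with an estimated correlation.

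Of 7 niche factors, 4 were higher and 1 lower, and 5 and 1 adjusted over the list alone. With both pools together, the list stood at 4266 CPM in megakaryocyte-like and 1291 CPM in macrophage-like cells for first barcode numbers 1 to 6. For numbers 7 to 12 it stood at 1534 CPM (983 to 2283) and 928 CPM (626 to 1325), with overlapping intervals. Angpt1, angiopoietin 1, which maintains blood stem cells and is also on the stem cell marker list (chromosome 15, 42424723 to 42676977), was higher, with 163 and 297 counts in megakaryocyte-like, 0 and 2 in erythroid-like and 3 and 1 in macrophage-like sums. Tgfb1, a growth inhibitor (chromosome 7, 25687002 to 25705077), had 66 and 114 counts in megakaryocyte-like and 0 counts in erythroid-like sums, and differed from macrophage-like cells alone by 0.87 ± 0.53 (edgeR adjusted p = 0.187). Pf4 is a megakaryocyte marker and describes the class. Cxcl12, also a stroma marker, was lower (-1.49 ± 0.51) but stood at 1.86 without pool 1. The list's median log2 of 3.72 became 0.04 with genes at 0 counts in a class set to 3 counts per sum. The list's camera adjusted p was 0.00341; the adjusted p was 0.228 with an estimated correlation.

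Of 10 megakaryocyte transcription factors, 4 were higher and 1 lower by either adjustment. Fli1 (chromosome 9, 32422204 to 32542861) was higher by 2.55 ± 0.31, and by 3.36 ± 0.47 against erythroid-like cells alone. Gata1 and Tal1, which red cell precursors also use, had 0 counts in macrophage-like sums, and against erythroid-like cells alone they differed by 0.70 ± 0.58 and -0.091 ± 0.60. Runx1 was lower (-1.09 ± 0.32), but was called higher with DESeq2 size factors (0.82) and with TMM over all genes (0.92), so its direction depends on the scaling. The list's median log2 of 2.25 became 0.66 with genes at 0 counts set to 3 counts. The list's camera adjusted p was 0.0176; the adjusted p was 0.300 with an estimated correlation, and 0.213 against erythroid-like cells alone at the preset correlation.

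Of 5 cell cycle genes, 3 were lower by either adjustment. Top2a, a DNA topoisomerase of dividing cells (chromosome 11, 98992943 to 99024189), was lower, with 3 and 1 counts in megakaryocyte-like and 14 and 14 in erythroid-like sums. Mki67 led the erythroid-like cluster and describes it. Cdk1 had 0 counts in megakaryocyte-like sums, with upper limits of 35.3 and 20.8 CPM. The list did not pass as a whole (camera adjusted p = 0.138).

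MHC class I genes, which present peptides to cytotoxic T cells, stood at 584 and 667 CPM in megakaryocyte-like, 755 and 815 CPM in erythroid-like and 4080 and 4366 CPM in macrophage-like cells. These sums hide a split, examined only after the data were seen: megakaryocyte-like cells stood at 407 and 543 CPM for first barcode numbers 1 to 6 and at 3393 and 2856 CPM for numbers 7 to 12. Macrophage-like cells stood at 1770 and 1405 CPM for numbers 1 to 6 and at 4998 and 5121 CPM for numbers 7 to 12, so the difference between classes is mixed with one between numbers. Of 10 tested, 5 were lower by either adjustment, of which Psmb8 held under all 4 scalings. Psmb8 had 0 counts in megakaryocyte-like, 1 and 0 in erythroid-like and 3 and 9 in macrophage-like sums. Against erythroid-like cells alone it was not called (-4.29 ± 2.16, edgeR adjusted p = 0.107). The list had a camera adjusted p of 0.171. Against macrophage-like cells alone, a comparison added after seeing the data, 10 of 10 were lower (camera adjusted p = 7.81e-05; adjusted p = 0.126 with an estimated correlation). B2m, the class I light chain (chromosome 2, 122147686 to 122153083), was lower there (-3.03 ± 0.46) and differed from erythroid-like cells by -0.24 ± 0.85. Calr, a chaperone of class I loading (chromosome 8, 84841850 to 84846934), was lower than in each class, by -2.46 ± 0.60 and -2.70 ± 0.58. Against erythroid-like cells alone, 3 of 10 (Calr, Pdia3 and Tap2) were lower and the list had a camera adjusted p of 0.872. Calr and Pdia3 held 5 and 3 of 14 erythroid-like list counts in pool 1, and 9 and 4 of 20 in pool 2. In megakaryocyte-like sums they held 7 and 4 of 61, and 23 and 12 of 118. H2-D1 and H2-K1 differed from erythroid-like cells by 1.24 ± 1.36 and 0.12 ± 1.56 and were not called (edgeR adjusted p = 0.478 and 0.961).

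MHC class II genes, which present peptides to helper T cells, stood at 47.8 and 33.9 CPM in megakaryocyte-like cells, 108 and 40.7 CPM in erythroid-like cells and 3913 and 6324 CPM in macrophage-like cells. Macrophage-like cells with first barcode numbers 1 to 6, where most megakaryocyte-like cells lie, stood at 590 and 602 CPM (3 counts in each pool). Those with numbers 7 to 12 stood at 5232 and 7784 CPM, so the size of this difference too is mixed with the number. Its direction was the same within each range. With both pools together, megakaryocyte-like cells stood at 37.6 CPM (upper limit 69.2) for numbers 1 to 6. Macrophage-like cells stood there at 596 CPM (219 to 1297), from 2 of 15 cells. For numbers 7 to 12 the levels were 63.9 CPM (1 count, upper limit 356) and 6774 CPM (5906 to 7733). These intervals cover counting error only. Of 8 tested, 3 were lower by either adjustment (camera adjusted p = 0.842). Each of these 3 had 1 count in erythroid-like sums. H2-Ab1, at 0 counts in megakaryocyte-like and erythroid-like sums, could not be called against the mean of both classes. Its SE of 10707.5 only restates a very small test statistic. Genes of the MHC class I and leukocyte lists at 0 counts in erythroid-like sums were not called lower either. Against macrophage-like cells alone 8 of 8 were lower (camera adjusted p = 6.21e-06, and 0.272 with an estimated correlation). H2-Aa, a class II chain (chromosome 17, 34282744 to 34287823), had 0 counts in megakaryocyte-like and 6 and 14 in macrophage-like sums. Cd74 and H2-Ab1 led the macrophage-like cluster and describe it.

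Interferon gamma response genes stood at 1512 and 1130 CPM in megakaryocyte-like cells, against 270 and 285 CPM in erythroid-like and 3410 and 4447 CPM in macrophage-like cells. Jak2 alone held 66 of the 158 and 121 of the 200 counts of the list in megakaryocyte-like sums. For first barcode numbers 1 to 6 megakaryocyte-like cells stood at 987 and 997 CPM, and for numbers 7 to 12 at 9856 CPM (4835 CPM without the 1 cell that held 40 of 61 counts) and 3491 CPM. Macrophage-like cells stood at 197 and 803 CPM (1 and 4 counts) for numbers 1 to 6 and at 4686 and 5377 CPM for numbers 7 to 12. With both pools together, megakaryocyte-like and macrophage-like intervals overlapped for numbers 1 to 6 (877 to 1120.5 and 161 to 1159 CPM). They also overlapped for numbers 7 to 12 (4856 to 7354 and 4354 to 5944 CPM). The order of the 2 classes in the whole sums is therefore not resolved within either range. Of 12 tested, 2 were higher, and 1 adjusted over the list alone (camera adjusted p = 0.161). Jak2, a kinase of cytokine receptors (chromosome 19, 29251828 to 29313080), was higher against both classes together and against each alone, with 66 and 121 counts in megakaryocyte-like, 3 and 1 in erythroid-like and 1 and 2 in macrophage-like sums. Irgm2, an interferon-inducible GTPase (chromosome 11, 58199618 to 58222782), had 36 and 36 counts in megakaryocyte-like and 0 in erythroid-like sums, and differed from macrophage-like cells by -0.23 ± 0.65. It overlaps Igtp (58199556 to 58207591), and how shared reads were counted is not given in the sources used here. Against erythroid-like cells alone the list had a camera adjusted p of 0.0422 (adjusted p = 0.398 with an estimated correlation) and a median log2 of 2.28, which became -2.11 with genes at 0 counts set to 3 counts (9 of 12 genes), so the list's direction there is not resolved at this depth. Against macrophage-like cells alone 9 of 12 were lower and 1 higher (camera adjusted p = 0.00414; adjusted p = 0.350 with an estimated correlation).

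Of 9 leukocyte genes, 2 were lower and 1 adjusted over the list alone (camera adjusted p = 0.842). Under all 4 scalings 0 were lower, and the DESeq2 Wald test called 1 higher and 0 lower. Laptm5 was called higher with each of the other scalings. Ptprc, encoding CD45 (chromosome 1, 138062861 to 138175708), had 3 and 3 counts in megakaryocyte-like and 19 and 18 in macrophage-like sums (edgeR adjusted p = 3.29e-25 against macrophage-like cells alone). Against macrophage-like cells alone 6 of 9 were lower (camera adjusted p = 0.00117; adjusted p = 0.138 with an estimated correlation). Of 5 p53 and apoptosis genes, Bcl2l1, which restrains cell death (chromosome 2, 152780668 to 152831728), was higher, with 36 and 62 counts in megakaryocyte-like, 0 and 1 in erythroid-like and 1 and 4 in macrophage-like sums (camera adjusted p of the list = 0.451). Against macrophage-like cells alone 0 of these 5 genes were called. Of 3 cytokine genes, Tgfb1 was higher (camera adjusted p = 0.161). Neither of 2 type I interferon genes nor any of 3 costimulation genes passed edgeR's adjusted or unadjusted threshold with the scaling used (camera adjusted p = 0.842 for both lists). The DESeq2 Wald test called 0 and 1 of them, and Cd47, of the costimulation list, was called higher by edgeR with DESeq2 size factors and with TMM over all genes. The cytotoxic and the immediate early list had 1 tested gene each, Ccl5 and Hsph1, too few for camera; Hsph1, the only tested gene of its list, did not pass (edgeR adjusted p = 0.0690; unadjusted p = 0.0324), with 2 and 5 counts in megakaryocyte-like, 0 and 4 in erythroid-like and 0 and 2 in macrophage-like sums. Median and camera test differed in sign for 5 lists. The medians of the interferon gamma (-0.97), type I interferon (-0.15) and p53 lists (-0.076) lay above the -1.05 of all genes, as camera's direction does. Those of the MHC class II (-4.22) and leukocyte lists (-1.27) lay below it. In these lists 6 of 8 and 4 of 9 tested genes were at 0 counts in a class. Fitted log2 values of such genes are not resolved, so neither sign is read as a direction.

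**Figure D3:**
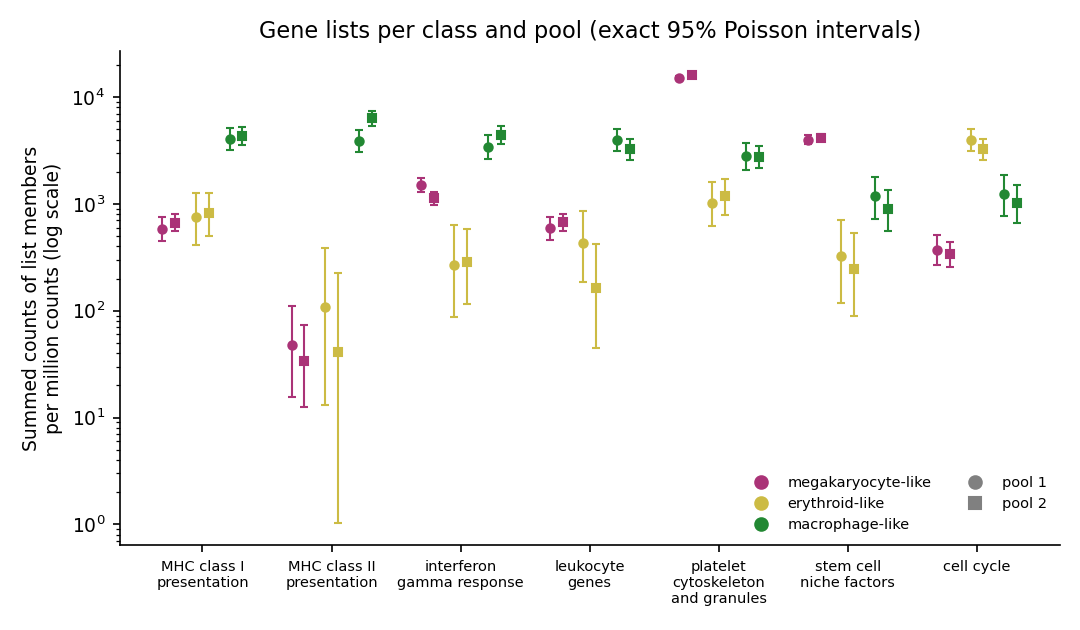
Summed counts of the members of 7 gene lists as CPM (y axis, log scale) by list (x axis), for 3 classes (colours) in pool 1 (circles) and pool 2 (squares); error bars are exact 95% Poisson intervals. MHC class II genes stood at 47.8 and 33.9 CPM in megakaryocyte-like and at 3913 and 6324 CPM in macrophage-like cells.

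Since the series concerns immune features of megakaryocytes, the share of megakaryocyte-like cells with a UMI of immune genes was set beside erythroid-like cells with every cell thinned to 200 UMIs. An MHC class I UMI was found in 7.89% of megakaryocyte-like cells in pool 1 (9 of 114, 3.67 to 14.5) and 9.80% in pool 2 (15 of 153, 5.59 to 15.7). These shares lay below the 10.3% (4 of 39, 2.87 to 24.2) and 14% (7 of 50, 5.82 to 26.7) of erythroid-like cells, with overlapping intervals. In macrophage-like cells the shares were 52.8% and 47.2%. An MHC class II UMI was found in 2 of 114 megakaryocyte-like cells and in 0 of 153 (upper limit 2.38%), and in 0 of 39 and 0 of 50 erythroid-like cells (upper limits 9.03% and 7.11%); without thinning the shares were 4.39% and 3.92% against 5.13% and 2%. Leukocyte gene UMIs were found in 7.89% (3.67 to 14.5) and 12.4% (7.64 to 18.7) of megakaryocyte-like cells and in 5.13% (0.627 to 17.3) and 4% (0.488 to 13.7) of erythroid-like cells, with overlapping intervals in both pools. Median depths were 772 and 710 UMIs in megakaryocyte-like and 444 and 451.5 UMIs in erythroid-like cells, and thinning left out 0 cells of either class. Without thinning, the MHC class I shares were 27.2% and 30.7% in megakaryocyte-like and 25.6% and 30% in erythroid-like cells, and the leukocyte shares 32.5% and 34.0% against 15.4% and 8%. Thinned to 400 UMIs, which left out 17 and 28 megakaryocyte-like and 18 and 15 erythroid-like cells, the leukocyte shares were 13.4% and 21.6% against 14.3% and 2.86%, so they differed in direction between the pools. Over all megakaryocyte-like cells thinned to 200 UMIs, the MHC class I share did not exceed that of erythroid-like cells in either pool. That share is of the whole list. Calr and Pdia3 held 5 and 3 of its 14 erythroid-like counts in pool 1, and 9 and 4 of 20 in pool 2. The share therefore does not compare the other class I genes alone. By first barcode number, without thinning, an MHC class I UMI was found in 23 of 106 and 36 of 136 megakaryocyte-like cells with numbers 1 to 6 (median 774.5 and 756.5 UMIs), and in 8 of 8 and 11 of 17 with numbers 7 to 12 (at lower median depth).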

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

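The tests of cluster 7 and of macrophage-like cells sharing a barcode were chosen only after the result was seen. No biological explanation was tested for these patterns, since the labels give 1 group.

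Counts in the unnamed clusters 3, 5, 6 and 10 followed gene length (Spearman correlation 0.687, 0.714, 0.708 and 0.917; 0.448 in cluster 7). Smell receptor genes, which the comparisons do not use, gave a signal in the unnamed clusters together: 2099 counts over 328 genes, 0.591 times the number expected from length (0.566 to 0.617). Unspliced nuclear RNA of marrow cells should leave these genes at 0.1 times or less, and the value argues against it as the source. Cluster 10 held 1786 of these counts. The values of clusters 3, 5, 6 and 10 lay between 0.511 and 0.652. Reads from genomic DNA, for which at least 0.5 times was set beforehand, may account for clusters 5 and 10, with lower limits of 0.541 and 0.588. Clusters 3 and 6 had lower limits of 0.484 and 0.41, under that level, so whether DNA alone accounts for them is not decided. Cluster 7, at 0.0523 (0.0210 to 0.108), lay below the level DNA alone would need. Its upper limit did not fall under 0.1, so a smaller part of such reads stays open there. The same holds for the megakaryocyte-like clusters 4 and 9, at 0.124 (0.0722 to 0.198) and 0.0953 (0.0310 to 0.222). It also holds for the macrophage-like cluster, at 0.0981 (0.0536 to 0.165).

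Among 936 kept cells, 131 shared 2 of 3 barcode numbers with a barcode of the same pool at least 10-fold larger, a signal outside the comparisons, against 25 in a search with shifted numbers. Counts carried over from the larger barcode may add to the excess. Their cluster equalled the partner's in 14.5% of pairs, and shuffled partners reached 14.5% at the upper limit, so the test left this open: 120 of the 131 partners were in cluster 10, which leaves little to shuffle. For 14 kept cells the same full barcode was at least 10-fold larger in the other pool. Cells with either kind of partner made up 25.4% of unnamed and 7.87% of erythroid-like cells, 8 of 267 megakaryocyte-like and 0 of 72 macrophage-like cells.

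Barcodes under 200 genes, which the comparisons leave out, held 957 MHC class II counts, 36.2% of their MHC class I and II counts (34.4 to 38.1). In megakaryocyte-like cells the class II part was 5.79% (2.93 to 10.1), and in macrophage-like cells 55.6% (50.6 to 60.5). Free RNA of the common pool and macrophage-like cells sharing a barcode would each bring class II counts at their own ratio. Over all first barcode numbers the value lay below both. For numbers 1 to 6, macrophage-like cells had 6 class II and 16 class I counts, against 10 and 131 in megakaryocyte-like cells. For numbers 7 to 12 these were 219 and 164 against 1 and 48. Limits within a range were not computed, and barcodes under 200 genes were not split by number. Most megakaryocyte-like cells have numbers 1 to 6. There the test does not decide whether either was a source of their MHC class I UMIs. Expression of class I genes by megakaryocyte-like cells themselves stays open as a hypothesis that was not tested, and a part from either source is not excluded. Erythroid-like cells, the class set beside them, had a class II part of 8.11% (1.70 to 21.9).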

How the results depend on the processing

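The alternatives with other low-count filters than none, TMM over all genes, library totals, shared barcode numbers, ribosomal-like genes, the naming rule used at first, the first barcode number, single classes and left-out clusters were chosen after seeing the data. Of the results that answer a comparison, 137 values under planned and 133 under added alternatives kept their side and direction or stayed within their interval. Beyond these, 23 and 22 moved, 3 and 4 became weaker, 3 and 9 stronger, and 0 and 4 reversed. Among the single genes reported, 302 and 368 values stayed the same and 12 and 28 reversed. A further 22 and 33 became weaker, and 6 and 27 stronger. The cause was not tested unless stated. With at least 500 genes no class reached 30 cells per pool, so no test was made, and leaving out a pool left values without a test. The alternatives of the comparison of BMF with normal mice were not run. With the pool as a replicate block, 21 list members were higher and 14 lower, against 22 and 16 without, and no list call changed. Medians are of fitted values. With genes at 0 counts in a class set to 3 counts they became 0.04 for niche factors, 0.66 for transcription factors, 2.00 for platelet genes, -3.43 for interferon gamma, -0.86 for cytokine, -5.24 for MHC class II, -1.98 for leukocyte and -2.25 for MHC class I genes, and stayed at -3.68 for the cell cycle and -0.076 for p53 genes. Over the alternatives, camera adjusted p ran from 2.97e-23 to 0.108 for platelet genes, from 6.49e-06 to 0.307 for niche factors and from 4.88e-11 to 0.777 for transcription factors. It ran from 3.56e-04 to 0.368 for the cell cycle, from 7.81e-05 to 0.872 for MHC class I, from 6.21e-06 to 0.989 for MHC class II, from 3.36e-04 to 0.977 for interferon gamma, from 0.00117 to 0.927 for leukocyte, from 0.0473 to 0.959 for cytokine and from 0.0167 to 0.857 for p53 genes.

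With at least 500 genes, erythroid-like cells fell to 0% and 0%, unnamed cells took 68.2% and 63.6%, and megakaryocyte-like cells with MHC class II or leukocyte UMIs in pool 1 were 0% and 0%. Without clusters 3, 5, 6 and 10, which follow gene length, megakaryocyte-like cells were 51.6% and 53.1%, erythroid-like 17.6% and 17.4%, macrophage-like 16.3% and 12.5%, and unnamed 14.5% and 17.0%, from the smaller total by construction. At resolution 0.5, erythroid-like cells were 0% and 0% and unnamed cells 61.9% and 63.7%. Without barcodes sharing numbers with a far larger one, pool 2 had 33.4% megakaryocyte-like and 47.5% unnamed cells, and the cell cycle median was -3.47 (camera adjusted p = 0.0436). Under the naming rule used at first, macrophage-like cells were 0% and 0% by construction, and unnamed cells 39.6% and 41.0%. Without thinning, MHC class I UMIs were found in 27.2% and 30.7% of megakaryocyte-like cells, leukocyte UMIs in 32.5% and 34.0%, and MHC class II UMIs in 3.92% in pool 2. At 400 UMIs, class I shares were 18.6% and 16%, the class II share in pool 1 was 0%, and the leukocyte share in pool 2 was 21.6%. Deeper cells hold more UMIs by construction, but the class II share of pool 1 went the other way. It was 0 of 97 cells at 400 UMIs, against 2 of 114 at 200 UMIs, each from 1 random draw.

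DESeq2 size factors gave 35 higher and 7 lower members and a cell cycle median of -1.77 (camera adjusted p = 0.0497). There the log2 values reversed to 0.26 for B2m, 1.45 for Cd47, 0.41 for Cxcl12, 0.82 for Runx1 and 1.62 for Zfpm1. TMM over all genes gave 36 and 6 and a cell cycle median of -1.67 (camera adjusted p = 0.0448), with 0.36 for B2m, 1.55 for Cd47, 1.58 for Coro1a, 0.51 for Cxcl12, 0.92 for Runx1 and 1.72 for Zfpm1. In both, the median of all genes moved above 0. The DESeq2 Wald test gave 8 lower members, with 0.29 for B2m, 1.48 for Cd47, 0.43 for Cxcl12, 0.85 for Runx1 and 1.62 for Zfpm1. Without Scrublet calls 10 members were lower and Cxcl12 stood at 1.93. Without pool 1 Cxcl12 stood at 1.86, and without pool 2 at -1.79.

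With edgeR's default filter, which left 427 genes, 8 members were lower, and the list calls were lost at medians of 2.67 for megakaryocyte transcription factors, 3.02 for platelet cytoskeleton and granules and 3.84 for stem cell niche factors (camera adjusted p = 0.777, 0.0767 and 0.307). With an estimated correlation the same medians of 2.25, 2.31 and 3.72 had camera adjusted p of 0.300, 0.108 and 0.228. With no filter, the MHC class I presentation median of -1.91 (camera adjusted p = 0.0191) and the cell cycle median of -3.52 (3.56e-04) passed.

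Against erythroid-like cells alone 8 members were lower. The cell cycle median was -4.94 and the interferon gamma median 2.28, both past the threshold (camera adjusted p = 0.0327 and 0.0422; 0.295 and 0.398 with an estimated correlation). The transcription factor median was 0.55 (0.213), and Tal1 was at -0.091. Against macrophage-like cells alone 14 were higher and 44 lower. Medians were -3.62 for MHC class I, -7.69 for MHC class II, -4.70 for interferon gamma and -3.71 for leukocyte genes, the last 3 opposite in camera direction to the mean over classes. There Cd274 was at -3.52, Irgm2 at -0.23 and Stat2 at -3.03.

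With the naming rule used at first and 50 cells, the only class compared was the T cell-like cluster 10, whose counts follow gene length; 50 members were higher and 30 lower over 15179 genes. The MHC class I presentation median reversed to 1.87 (camera adjusted p = 4.42e-04), and those of interferon gamma response (0.68) and p53 and apoptosis (0.28) passed (3.36e-04 and 0.0167). Genes reversed to 3.23 for B2m, 3.43 for Calr, 2.40 for Cd47, 3.17 for Coro1a, 3.37 for Cxcl12, 2.87 for H2-D1, 1.82 for Ifit2, 1.60 for Itgb2, 2.04 for Lyz2, 3.94 for Mcl1, 1.63 for Mki67, 1.03 for Runx1, 0.16 for Tap2, 3.19 for Tapbp and 2.38 for Zfpm1. With that rule and 30 cells, the cell cycle median of -3.31 and the cytokines and chemokines median of -1.22 (camera direction up) passed (camera adjusted p = 0.0473 for both), and B2m was at 0.26, Cxcl12 at 2.46 and Lyz2 at 1.79.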

Other observations

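No test was made in this part, and all of its values were chosen after seeing the data.

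Marker lists of other cell types gave levels in megakaryocyte-like cells. Osteoclast markers stood at 3799 CPM in pool 1 and 3650 CPM in pool 2, against 559 and 286 CPM in macrophage-like cells; Itgb3 is on both the osteoclast and the megakaryocyte list. Stem and progenitor markers, which include Angpt1, stood at 1914 and 2119 CPM, against 540 and 285 CPM in erythroid-like cells. Dendritic cell markers stood at 679 and 887 CPM and neutrophil markers at 1043 and 1091 CPM. T cell markers stood at 47.8 and 50.9 CPM in megakaryocyte-like and at 894 and 1183 CPM in macrophage-like cells.

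The classes differed in the first barcode number. Megakaryocyte-like cells numbered between 33 and 49 for each first number from 1 to 6 and between 2 and 6 for each from 7 to 12. Erythroid-like cells numbered between 4 and 26 for each from 1 to 6 and 0 for each from 7 to 12. Macrophage-like cells numbered between 1 and 4 for each from 1 to 6 and between 6 and 15 for each from 7 to 12. Levels of some lists in megakaryocyte-like cells differed between these ranges. MHC class I genes stood at 493 CPM (131 counts, 412 to 585) for numbers 1 to 6 and at 3069 CPM (48 counts, 2263 to 4069) for numbers 7 to 12. Interferon gamma response genes stood at 993 CPM (877 to 1120.5) and 6009 CPM (4856 to 7354), or 3914 CPM without the cell with most counts. MHC class II genes stood at 37.6 and 63.9 CPM (10 and 1 counts, with overlapping intervals), and platelet genes at 16236 and 7800 CPM. Type I interferon response genes stood at 113 CPM (76.1 to 161) and 959 CPM (537 to 1582). In macrophage-like cells these genes had 0 counts for numbers 1 to 6 (upper limit 366 CPM) and stood at 1113 CPM (779.9 to 1542) for numbers 7 to 12, so no difference between the 2 classes is seen within either range. Cluster 4 held 15 of the 25 megakaryocyte-like cells with numbers 7 to 12 and 36 of the 242 with numbers 1 to 6, so the make-up of the class differs too. These values make the MHC class I and interferon levels of the whole class a mixture of 2 unlike ranges. Other immune lists had overlapping intervals. Leukocyte genes stood at 643 CPM (550 to 747) and 703 CPM (351 to 1258) for the lower and upper numbers. Cytokine genes stood at 737 CPM (638 to 848) and 511 CPM (221 to 1008), and costimulation genes at 508 CPM (426 to 601) and 831 CPM (443 to 1421). What the first number stands for is not given in the sources used here, and no condition was inferred from it.

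Of 405 barcodes with at least 200 genes in pool 1, 388 (95.8%) were also present in pool 2, at a median of 6.23% of their UMIs. Of 540 such barcodes in pool 2, 239 (44.3%) were also present in pool 1, at a median of 1.75%.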
